A study of Mus musculus with 6 samples.

How the data were processed

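Total RNA from the glandular stomach of 3 infected and 3 control BALB/c mice aged 3 to 4 weeks, taken 8 h after infection, was measured on 6 one-colour (Cy3) Agilent mouse miRNA arrays, per the labels. The labels give the mice as separate animals kept in cages of 3, and which mice shared a cage is not given in the sources used here, so the cage may coincide with the group. The labelling protocol in the labels describes amplified cRNA made with a kit for messenger RNA, although the arrays are miRNA arrays, so how the small RNA was labelled stays uncertain.

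The spot intensity values were made by the authors with Agilent Feature Extraction 10.7.1.1, per the file headers and the submitters' processing notes: background-subtracted linear signals with spatial detrending and no scaling between arrays. A spot is marked well above background at 13 times the background error, and a miRNA as detected at 3 times its error, per the file headers. The array design was annotated on the mm9 build, per the file headers. The deposited series matrix holds log2 values for 1902 entries. The sorted values are the same in every column, each column's median is -3.32, and 1493 entries lie at that minimum. Its Spearman correlation with the scanner files' total gene signal was 0.918 to 0.993 per array, which as a rank measure cannot show the scale. On the log2 scale the Pearson correlation was 0.940 to 0.975 per array, and the values were taken as log2. The columns were matched to the arrays by their sample names alone. The shared sorted values are what quantile normalization gives, although the method is not given in the sources used here. The series matrix was used only as an alternative.

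Control spots and spots marked as outliers were left out. The mean processed signal over the spots of a probe was averaged on the linear scale over the probes of a miRNA, covering 4415 probes and 56430 spots. No spot was saturated. A probe was above background when over a share of 0.5 of its spots were well above background, and a miRNA when at least 1 of its probes was. Each array was divided by its 75th percentile over the 220 miRNAs above background on all 6 arrays. These percentiles were 262, 185 and 214 in controls 1 to 3 and 259, 178 and 195 in infected mice 1 to 3. Values were then floored at the 1st percentile of values above background, 7.30, and log2 was taken. Scaled intensities in the text are before the floor. Tested were the 239 miRNAs (12.7%) above background on all 3 arrays of at least 1 group. The number of arrays limits the precision: the median SE of a log2 difference was 0.17.

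Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05 and no block. A count at an unadjusted p under 0.05 with an absolute log2 difference of at least 1 is given as a description. Lists were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry beside it, where at least 3 members were tested. For a miRNA not well above background on any array of a group, a fold was taken against the lowest signal above background on each array. The miRNA's own value was used where higher, so this fold is an estimate and not a strict bound. miRNAs named were the 10 with the smallest p in each direction among those above background on all 6 arrays (none passed, which left the part of the rule for called miRNAs empty), up to 3 members per list, the 5 with the highest mean signal, and miR-146a-5p, miR-155-5p, miR-21a-5p and miR-223-3p. The tests, the lists and this rule were fixed before the data were examined.

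The lists covered inflammation, a biliary set from Cryptosporidium parvum, the miR-200 family, gastrointestinal and squamous epithelium, smooth and striated muscle, neurons, myeloid and lymphoid cells, erythroid cells, endothelium, acinar pancreas, liver, the let-7 family, the miR-17-92 clusters, miR-34 and miR-449, the miR-29 and miR-30 families, hypoxia, miR-221 and miR-222, miR-23, miR-24 and miR-27, and the Dlk1-Dio3 and Sfmbt2 clusters. Host genes were taken by overlap from a RefSeq table on another mouse build, of which no coordinates are given, and positions are those of the probes in the files on mm9.

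The procedure was tested on simulated data with known changes in the 239 miRNAs over 20 draws. It recovered 97.5% of log2 changes of -2, 92% of -1, 85.5% of 1 and 99.5% of 2, and called 1.01% of unchanged miRNAs. A shifted list was called at an unadjusted camera p under 0.05 in 20 of 20 draws and an unshifted one in 0. The simulated noise was independent between miRNAs and every miRNA was set above background, unlike the real arrays. Its size came from limma's variance estimates, already drawn towards a common value. A tested miRNA that lay at the floor on every real array was therefore given noise too. Members of the real lists varied together, with an estimated correlation of 0.73 for the miR-29 and miR-30 families. The simulation therefore does not give the rate of false list calls here, and its recovery may be too high. Alternatives planned in advance changed the scaling, background correction, summary over spots and probes, source of the values, filter, detection mark, floor, variance model, block and set of arrays. Added after the data were seen were the slide row as a block, removal of each array's linear trend on probe GC share and length, scaling by spike-in controls, and leaving out miRNAs at the floor on every array. The last was added because a first version of the alternatives left such miRNAs out and gave 2 calls where the planned fit gave 0. The planned fit was kept. Plots were drawn with matplotlib 3.10.9.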

Results

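MicroRNAs (miRNAs) were profiled in the glandular stomach, the acid-secreting part of the mouse stomach, of young BALB/c mice sampled 8 h after infection with Cryptosporidium muris, a protozoan parasite that lives on gastric epithelium. Tissue from 3 infected and 3 control mice was hybridised one mouse per array to 6 Agilent mouse miRNA arrays carrying probes for 1881 mouse miRNAs. The comparison asks which miRNAs differ in the stomach early in infection. Between 239 and 310 miRNAs per control array and between 252 and 272 per infected array lay above background. The mean was 275.7 ± 35.6 (SD, n = 3) in controls and 263 ± 10.1 (SD, n = 3) in infected mice, a difference of -12.7 (two-sided exact permutation test p = 0.7, where the smallest p this design allows is 0.1). The difference was 4.5 without control 1, -31 without control 2 and -7.17 without infected 2. Of the 335 miRNAs above background on at least 1 array, 239 were above background in every mouse of at least 1 group and were tested. The brightest were miR-6366, miR-3963, the epithelial miR-200b-3p and miR-429-3p, and miR-21a-5p. miR-200b-3p had a scaled intensity of 3430 ± 337 (SD, n = 3) in controls and 3666 ± 617 (SD, n = 3) in infected mice.

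Most of the differences with the smallest p values were lower signals in infected mice, but no miRNA passed an adjusted p of 0.05. The nearest was miR-721, whose gene overlaps Cux1. Its scaled intensity was 77.0 ± 25.2 (SD, n = 3) in controls and 13.5 ± 5.18 (SD, n = 3) in infected mice, a log2 difference of -2.52 ± 0.35 (SE) with a limma adjusted p of 0.0595. miR-3099-3p, whose gene overlaps Usp29, had intensities of 29.1 ± 9.99 (SD, n = 3) and 7.06 ± 3.31 (SD, n = 3). It was not well above background on any infected array. Against the lowest signal above background on each array, or its own where higher, it was 3.96-fold lower there. This is an estimate from signals not well above background and not a lower bound. The fit, with its higher floor, gave 3.34-fold, with a limma adjusted p of 0.105. miR-721 was above background in 1 of the 3 infected mice. Both were chosen after their values were seen, since the naming rule required signal above background on all 6 arrays. The probes of miR-721, miR-3099-3p, miR-211-3p, miR-5126, miR-3102-5p and miR-8110, which had the 6 smallest p values, all hold a run of at least 4 C.

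limma called 0 miRNAs at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 22, of which 21 were lower and 1 higher in infected mice, while over all 239 tested miRNAs 102 point estimates were lower and 137 higher. Of the 22, 6 of the lower ones also differed by 2-fold or more. The groups did not overlap for 26 miRNAs that were lower and 3 that were higher, where chance gives 10% of the 239. The count of 0 rested on miR-338-5p, a tested miRNA whose values all lay at the intensity floor: its variance of 0 enters limma's estimate of the common spread. Without it, a setting chosen after this effect had been seen, limma called 2 miRNAs, with an adjusted p of 0.0140 for miR-721 and 0.0354 for miR-3099-3p. Over all alternatives the adjusted p of miR-721 ranged from 7.33e-07 to 0.706 and passed in 10 of 26. That of miR-3099-3p ranged from 5.94e-04 to 0.983 and passed in 8 of 26. Both were tested because they were above background in all 3 controls, so the filter used the groups. Filters blind to the groups gave 0 limma calls each. The lowest limma adjusted p was 0.295 among miRNAs above background on all 6 arrays, where neither was tested. It was 0.131 among those above background on at least 1 array and 0.342 with no filter. Without control 3 limma called 5 miRNAs, all lower in infected mice. The 2-fold count was 12 without control 2, 12 without control 3 and 3 without infected 1, and the count at an unadjusted p under 0.05 was 43 without control 2, 8 without infected 1, 56 without infected 2 and 10 without infected 3.

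Among miRNAs above background on all 6 arrays, the 10 with the smallest p values in the lower direction were named. miR-211-3p, encoded within Trpm1, the gene of a melanocyte and retinal cation channel, had 35.3 ± 1.89 (SD, n = 3) in controls and 17.5 ± 4.63 (SD, n = 3) in infected mice, a log2 difference of -1.04 ± 0.20 (SE, limma adjusted p 0.12). Its probe maps to chromosome 7 at 71350763 to 71350774 on the mm9 build. miR-494-3p, from the imprinted Dlk1-Dio3 cluster on chromosome 12 (110953585 to 110953598, mm9), had 810 ± 598 (SD, n = 3) in controls and 200.4 ± 52.0 (SD, n = 3) in infected mice, a log2 difference of -1.74 ± 0.57 (SE, limma adjusted p 0.403). The controls ranged widely for miR-494-3p, with 1458, 279 and 692 in controls 1 to 3, and the log2 difference was -1.15 without control 1 and -2.38 without control 2. miR-3473b (log2 difference -1.24), miR-7005-5p (-1.25), miR-3473a (-0.96) and miR-690 (-0.82) were also lower as point estimates. Without control 1 the difference was -0.74 for miR-7005-5p and -0.62 for miR-3473a. The probes of miR-3473a and miR-3473b share most of their sequence, so their values may not be independent. miR-5126 (-0.64), miR-3102-5p (-0.63), miR-8110 (-0.51) and miR-1231-5p (-0.35) completed the 10. None of them passed.

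In the other direction, miR-34a-5p, a transcriptional target of p53, had the smallest p value. Its intensity was 104.7 ± 16.5 (SD, n = 3) in controls and 178 ± 67.4 (SD, n = 3) in infected mice, a log2 difference of 0.71 ± 0.27 (SE, limma adjusted p 0.432), and every infected mouse lay above every control. Without infected 2 the log2 difference was 0.43. Its probe maps to chromosome 4 at 149442585 to 149442603 (mm9). miR-5100 (log2 difference 0.53), the endothelial miR-126a-3p from the Egfl7 locus (0.32) and miR-301a-3p (0.37) were higher as point estimates, as were miR-3098-5p (0.35), miR-125a-5p (0.35), miR-322-5p (0.31), miR-1839-3p (0.26), miR-141-5p (0.24) and miR-345-5p (0.23). Single arrays carried some of these: miR-125a-5p was at 0.06 without control 2, miR-345-5p at 0.11 without control 1, miR-3098-5p at 0.23 without control 3, and miR-301a-3p at 0.19 without infected 1 and 0.63 without infected 2.

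**Figure D1:**
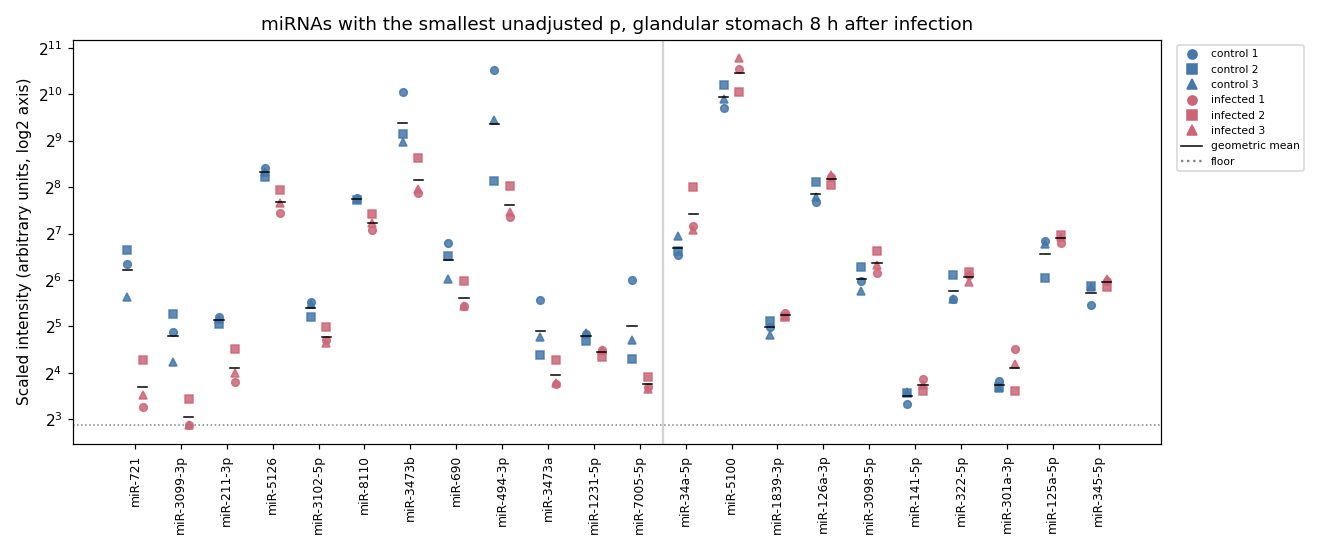
Scaled intensity (log2 axis, arbitrary units) of the named miRNAs on each array. Blue symbols are control mice 1 to 3, red symbols infected mice 1 to 3, black bars geometric means, and the dotted line the intensity floor of 7.30. miR-721 is highest in the controls with a mean of 77.0, against 13.5 in infected mice.

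All 6 arrays lay on 1 slide in 1 scan, but slide row 1 held the 3 infected mice and control 1, and row 2 held controls 2 and 3. With the slide row as a block, the comparison is that within row 1, of the 3 infected mice against control 1 alone, with the spread of the lone control taken to be that of the others. limma then called 6 miRNAs, all lower in infected mice: miR-3470a, miR-3473a, miR-3473b, miR-494-3p, miR-7005-5p and miR-7042-5p, of which miR-3470a and miR-7042-5p were named after their values were seen. miR-721 (log2 difference -2.65, limma adjusted p 0.0503) and miR-3099-3p (-1.83, limma adjusted p 0.0769) were not called there, and miR-34a-5p differed by 0.88. Control 1 stood apart in muscle and liver miRNAs, and controls 1 and 2 in the leukocyte miR-142a-3p, miR-150-5p and miR-155-5p.

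The split between directions depended on how arrays were scaled. Scaling by the median over miRNAs above background gave 12 lower among 18 at an unadjusted p under 0.05. Quantile normalization gave 13 lower among 18, and removing each array's trend on probe GC share and length gave 13 lower among 23. That removal also gave every array the same mean over the tested miRNAs. The split stayed at 16 lower among 17 with no scaling, 12 among 13 with the 75th percentile over all miRNAs and 15 among 15 with spike-in scaling. Across the 239 tested miRNAs, the log2 difference had a Spearman correlation of -0.38 with probe GC share and 0.42 with probe length. The GC trend was not shared by the infected arrays. Each array's deviation from the miRNA means correlated with GC share at -0.55, 0.45 and -0.38 in infected 1 to 3. In controls 1 to 3 it was 0.06, 0.24 and 0.38. miRNAs are not independent replicates. Without control 1 the same count was 13 lower among 20, and without infected 2 it was 27 lower among 56, so that most were then higher.

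**Figure D2:**
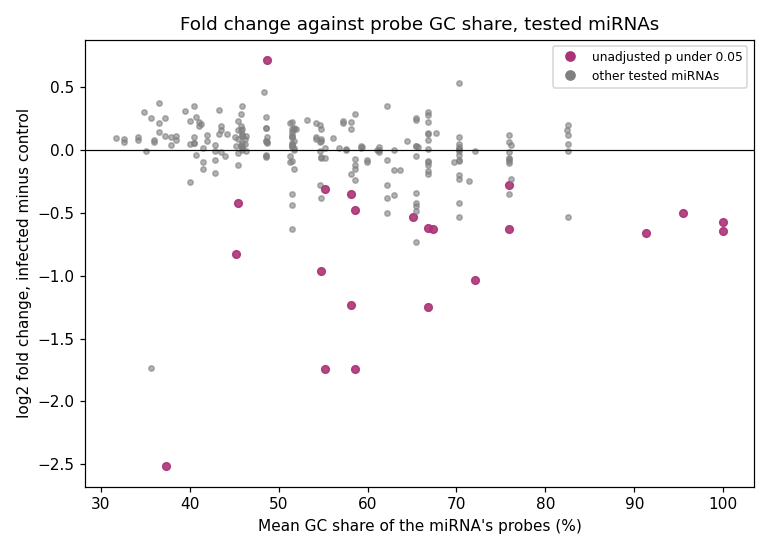
Log2 difference (infected minus control) of each tested miRNA against the mean GC share of its probes in percent. Purple points are the 22 at an unadjusted p under 0.05, grey points the other tested miRNAs. The Spearman correlation across miRNAs is -0.38.

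Of 22 lists fixed before the data were examined, 11 had at least 3 tested members, and 1 was called. In the miR-29 and miR-30 families, all 10 tested members were higher in infected mice as point estimates, with a median log2 difference of 0.19 and a camera adjusted p of 0.00570. With an estimated correlation the p was 0.247, and the adjusted p 0.889, so that call did not hold there. miR-30e-5p differed by a log2 value of 0.26 and miR-30a-5p by 0.22. Without infected 2 these were 0.43 and 0.35 and the list median 0.32, and without infected 1 they were 0.17 and 0.15 and the median 0.13. No list was called with an estimated correlation or by fry, nor without scaling between arrays, with the 75th percentile over all miRNAs, normexp, the series matrix or spike-in scaling, or without infected 1, while 4 were called without control 3 and 5 without infected 2. Without control 1 the call of the miR-29 and miR-30 families was lost and the Sfmbt2 cluster was called, with members higher. That call did not hold with an estimated correlation. The miR-200 family, markers of epithelium, had 8 of 8 members higher as point estimates with a median of 0.14 (camera adjusted p 0.107). The gastrointestinal epithelium list had 7 of 7 higher with a median of 0.22, led by miR-7a-5p at 0.30 (camera adjusted p 0.107), which was at 0.17 without infected 1 and 0.53 without infected 2. The 15 tested members of these epithelial lists had a median log2 value of -0.27 on control 1 relative to the other arrays, and without control 1 the list medians were 0.07 and 0.09. They were 0.09 and 0.10 without infected 1, 0.25 and 0.47 without infected 2, and 0.09 and 0.15 without infected 3. The let-7 family had 9 of 9 higher with a median of 0.09 (camera adjusted p 0.190), which was 0.03 without infected 1 and 0.21 without infected 2.

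The inflammation list gave 9 tested members with a median of 0.16 (camera adjusted p 0.215) and included miR-212-3p at 0.28 and miR-132-3p at 0.16. Its median was 0.02 without control 2 and 0.26 without infected 2, and miR-212-3p was at 0.43 without infected 2 and 0.16 without infected 3. The biliary list drawn from Cryptosporidium parvum infection had a median of 0.05, the clusters of miR-17-92 and its paralogues 0.07, the miR-23, miR-24 and miR-27 list 0.03, the erythroid list 0.03, the leukocyte list -0.16 and the Sfmbt2 cluster 0.03. None of these was called, and leaving out 1 array turned the sign of each of the last 6, with -0.03 for the biliary list without infected 1, -0.01 for the miR-17-92 clusters without control 3, -0.04 for the miR-23 list without infected 1, -0.04 for the erythroid list without control 3, 0.06 for the leukocyte list without infected 2 and -0.26 for the Sfmbt2 cluster without control 2. Other arrays left out gave calls: the leukocyte list without control 3 (median -0.34, camera adjusted p 0.0333) and the biliary list without infected 2 (0.18, camera adjusted p 0.0385). Neither call held with an estimated correlation. Of the small lists, the squamous members miR-203-3p and miR-205-5p differed by -0.26 and -0.19, the endothelial miR-126a-3p by 0.32, the hypoxia-linked miR-210-3p by 0.03, miR-221-3p by 0.05, and the smooth muscle miR-143-3p by -0.16. The squamous values were -0.06 and -0.01 without infected 2, that of miR-143-3p 0.41 without control 1, and those of miR-210-3p and miR-221-3p turned sign without control 3. Adjusted over the list alone, miR-34a-5p (0.0362) and miR-494-3p (0.0422) passed, the first as the single tested member of the miR-34 and miR-449 list. The Dlk1-Dio3 list of miR-494-3p had 2 tested members, and the other, miR-341-3p, was higher in infected mice, at 0.26. Over all 239 miRNAs neither miR-34a-5p nor miR-494-3p passed. The striated muscle, neuron and liver lists had members above background on at least 1 array but no tested member, and no acinar pancreas miRNA was above background on any array.

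Of the immune miRNAs named in advance, miR-21a-5p had 2822 ± 275 (SD, n = 3) in controls and 3056 ± 834 (SD, n = 3) in infected mice, and miR-223-3p 36.4 ± 9.92 (SD, n = 3) and 31.9 ± 1.34 (SD, n = 3). miR-146a-5p and miR-155-5p were not tested, with 1 and 1 control arrays and 2 and 0 infected arrays above background. Control 1 stood apart in muscle and liver miRNAs: miR-143-3p measured 161 there and at most 75.4 on any other array, miR-145a-5p 25.6 against at most 9.30, miR-133a-3p 16.1 against at most 8.29, and the liver miR-122-5p 15.9 against at most 4.06. The leukocyte miR-142a-3p measured 95.1 in control 1 and 47.7 in control 2, while control 3 was within the range of the infected mice, which measured 13.9, 7.30 and 13.3 (log2 difference -1.73, limma adjusted p 0.522; -1.02 without control 1 and -2.61 without control 3). Of the 96 miRNAs above background somewhere but not tested, 45 were highest on control 1.

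**Figure D3:**
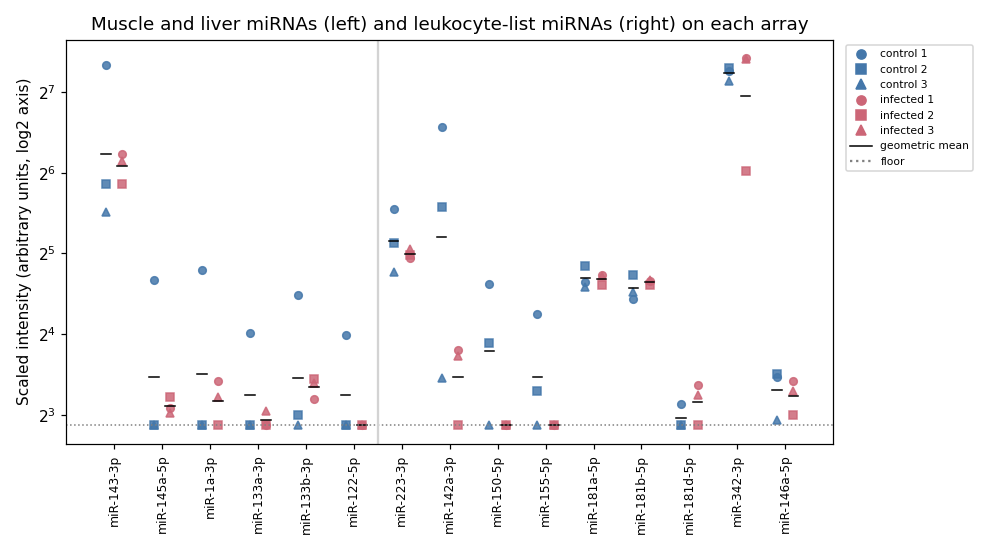
Scaled intensity (log2 axis, arbitrary units) per array of muscle and liver miRNAs, left of the line, and leukocyte-list miRNAs, right of it. Symbols are the 6 mice, bars geometric means, and the dotted line the floor. miR-143-3p reads 161 on control 1 and at most 75.4 elsewhere.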

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

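Chosen after the data were seen were the slide row block, the GC and length correction, spike-in scaling and leaving out miRNAs at the floor on every array. Against 0 calls as planned, limma called 2 miRNAs with the 75th percentile over all miRNAs, 1 with the median, 2 with no scaling, 5 with normexp, 2 with the median over spots, 2 with robust eBayes, 6 with the slide row as a block (infected mice against control 1 alone), 5 with spike-in scaling and 2 without miRNAs at the floor on every array. All these calls were lower in infected mice. Leaving out 1 array gave 0 to 5. The 2-fold count of 6 became 2 with normexp, 11 with the software's detection mark, 18 with the slide row block, and 3 to 12 without 1 array. The 1 called list became 0 with the 75th percentile over all miRNAs, with no scaling, with normexp, with the series matrix and with spike-in scaling, 2 with the software's detection mark, 3 with the slide row block and 0 to 5 without 1 array. It became 9 with no filter, where 1471 of 1881 miRNAs lay at the floor on every array. None of these list calls held with an estimated correlation. With the replicate block limma called 2 miRNAs. Deviations of same-numbered mice correlated at 0.00, -0.02 and -0.21, which shows no shared deviation but cannot tell whether the numbers paired the mice. The Sfmbt2 median turned to -0.99 with the slide row block. The difference in miRNAs above background ranged from -31 to 4.5 without 1 array. Other than where stated, the cause was not tested. A slide or scan block was not run, as there was 1 of each. Of the values of named miRNAs under alternatives, 1583 kept their direction and side of the threshold, 85 changed sign without a call and 30 passed it. Signal over background limits the low miRNAs: 1881 were on the array and 239 could be tested.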

Other observations

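The tests of probe GC share, of runs of C over all tested miRNAs, of control 1 alone, of the slide row, and of muscle, liver and leukocyte content were chosen after the results were seen. The 21 miRNAs lower in infected mice at an unadjusted p under 0.05 had a median log2 difference of -0.63. Removing each array's trend on probe GC share and length left -0.46 (95% bootstrap interval over these miRNAs -0.84 to -0.34). They were chosen from these same values for being low, so what is left cannot show how much of the pattern the trend accounts for. With the trend removed, 13 of the 23 at an unadjusted p under 0.05 were lower, against 21 of 22 before. The removal also gave every array the same mean over the tested miRNAs, as a change of scaling does. Scaling by the median over miRNAs above background gave 12 lower among 18 with no such removal. The shift from 21 of 22 therefore cannot be credited to GC share and length. Probes with 4 or more C in a row were present for 10 of these 21 and for 20 of the other 218 tested miRNAs, while the other 11 have no such run and a median of -0.63. Over all tested miRNAs, the log2 median of such probes differed from others of like GC share by -0.185 (-0.34 to -0.07, permutation p = 0.0006). These 10 take part there and prompted the test. Outside the 21, where the lowest were left out, it differed by -0.089 (-0.21 to -0.01, permutation p = 0.0167). Both tests shuffled and resampled miRNAs and not arrays, and miRNAs on the same arrays can vary together. Their p values and intervals therefore do not measure the spread between mice. Such probes lay lower on these arrays, but neither value decides whether the runs are the cause. Without control 1 the median of the 21 was -0.55 (-0.63 to -0.37). They were chosen with controls 2 and 3 as well, which lay in another slide row than the infected mice, so this cannot decide the part of control 1. At an unadjusted p under 0.05 without control 1, 13 of 20 were lower. With the slide row as a block the median of the 21 was -0.83 (-1.18 to -0.72), which cannot decide on the row. That comparison rests on 1 control array, which also helped to choose these miRNAs. Infection, the slide row, probe GC share and length, control 1, runs of C for those 10 and chance stay open. So does the cage, whose sharing is not given.

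Muscle and liver miRNAs were high on control 1, with a median log2 excess of 1.40 over 4 other arrays. Infected 1, with a scaling value of 259 against 262, had an excess of 0.0585 (-0.02 to 0.43), but 1 array cannot exclude a cause in the array. The 2 arrays also differed among dim miRNAs, with 310 above background on control 1 and 272 on infected 1. Of these, 25 and 7 were above background on that array only. All 6 of the 6 muscle or liver miRNAs above background on any array were highest on control 1. Of these, miR-145a-5p, miR-133a-3p and miR-122-5p were above background on 1 array only, so the filter itself may have fixed their rank. The 15 epithelial miRNAs had a median log2 value of -0.27 on control 1 relative to the other arrays. A candidate explanation is more muscle wall, with some liver, in that piece of stomach. These values do not decide it, and the liver part rests on miR-122-5p alone.

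The leukocyte miRNAs miR-142a-3p, miR-150-5p and miR-155-5p were high on controls 1 and 2. The 4 other leukocyte-list miRNAs above background on all arrays differed by a median log2 value of 0.18 (range -0.03 to 0.41), which may reflect leukocyte content of single mice but is too small to decide it. Control 3 differed from the infected mean in miR-142a-3p by -0.0116, so a difference due to infection cannot be told apart from one between mice with 3 controls.

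With 3 mice against 3 there are 10 splits of the arrays, too few for a share under 0.05. The planned fit called 0 miRNAs and the highest other split 0, so all 10 gave as many. The 2-fold count was 6 and the highest other 4, and 1 of 10 splits gave as many. For lists the count was 1 and the highest other 4, and 9 of 10 gave as many. The split of controls 1 and 3 with infected 2 from the rest gave 70 miRNAs at an unadjusted p under 0.05 against 22 for infection, which points to a structure among the arrays other than the groups.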
